A study of Mus musculus with 8 samples.

How the data were processed

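Total RNA of 8 livers, 4 per group, was measured on 1-colour Affymetrix Mouse Gene 2.0 arrays after Trizol extraction and biotin labelling. The groups, WT (AAV-GFP) and NCOR_KO (AAV-Cre), and the replicate numbers were taken from the sample labels. The labels name the controls wild-type, while the design text gives floxed mice to both viruses, so whether the controls carry the floxed allele is not settled here. The virus differs exactly with the group, so an effect of Cre itself cannot be parted from loss of NCOR.

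The deposited values are probe-set intensities on a linear scale, and the submitters' processing notes name RMA and Partek without saying what each did. Versions, background settings, filters and genome build were not given in the sources used here. Intensities ran from 5.42 to 13268, and log2 was taken, giving 2.44 to 13.70. No further normalization was applied. The median intensity of the arrays, 41.0 to 44.1, stands here for depth.

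The table held 41345 probe sets on 8 arrays. Of these, 25335 were assigned to a gene, and the 16010 without an assigned gene and 1814 with several genes were left out of the gene tests. Control probe sets could not be told from other unassigned ones. The 23521 with a single gene were set beside a RefSeq gene table on assembly GRCm38.p6: 23328 matched by gene identifier, 193 did not, and 0 symbols changed. For the 1082 genes with more than 1 probe set the one with the highest mean over all 8 arrays was kept, leaving 22180 genes, with no filter on dim ones.

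Both groups were compared with limma 3.58.1 on R 4.3.3 (lmFit, then eBayes without trend or robust settings; intercept and group). P-values were adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05, and a count of changes of at least 1.5-fold was taken beside it. All adjusted p-values for genes come from limma. Log2 changes are knockout minus control, and their errors are the standard errors of the fit. The tests, gene lists, named-gene rule and alternatives described here were set before the data were examined, unless stated otherwise.

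The gene lists, 35 in all and 10 of them cell type markers, were written from general knowledge of liver biology, and 631 of their 716 symbols were measured. Peci, Tbg and Igj were matched under the current symbols Eci2, Serpina7 and Jchain. The matching of older symbols was corrected after values had been seen, since it had paired Trf and Loxl2 with other genes; the hepatocyte marker list passed the threshold only after that correction. Lists with at least 5 measured members, 33 of 35, were tested with camera at its preset correlation of 0.01 and adjusted over all of them. Camera with a correlation estimated per list and fry were alternatives. A list score per array, the mean over members of the value minus the gene's mean over 8 arrays, was compared by exact permutation over 70 assignments, whose smallest p is 0.0286.

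Genes were named by a fixed rule. Among genes past the threshold with all 4 knockout values on one side of all 4 control values, and leaving out predicted or unnamed symbols, the 12 largest rises and the 12 largest falls were named. For each list up to 4 members with the largest change past the threshold were added, or, where none passed, the 1 with the largest change. A fixed set of lipid, bile acid, clock, glucose and complex genes was always named where measured. Some genes of that set are not reported here. Sex-linked genes, further clock genes and Abcc4 were chosen after their values were seen.

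Alternatives were quantile normalization, centring of each array on its median, array weights, a trend and robust variance, only genes at or above the median level, the mean of a gene's probe sets, the replicate number as a block, every probe set tested singly, thresholds of 0.01 and 0.1, a limma treat test against 1.2-fold, and leaving out each array in turn. Leaving out WT replicate 2 and NCOR_KO replicate 1 together was chosen after seeing the data. Up to 15 of these applied to each named gene, the added one not counted. All 35 splits of the arrays into 4 and 4 were refitted.

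The steps were tested on simulated data drawn from each gene's mean and spread, independently between genes, so correlation within lists was not part of that test. With 200 of 22180 genes changed, 26% of 50 genes changed 1.2-fold were called, 76% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, along with 8 unchanged genes. With no change planted 0 genes were called. Of 20 lists moved 1.15-fold 20 were called, also with an estimated correlation, and of 20 unmoved lists 0 were. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.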

Results

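Liver RNA was profiled on 8 single-colour expression arrays from 3-month-old mice on normal chow. The mice had received adeno-associated virus (AAV), a gene delivery vector that reaches hepatocytes, through a vein. In 4 of them the virus carried Cre recombinase, which excises the floxed part of the gene for NCOR, and in 4 controls, which the labels call wild-type, it carried GFP. Livers were taken 2 weeks later at 5 pm, which is ZT10 on the light schedule. NCOR is a corepressor that nuclear receptors recruit with the deacetylase HDAC3, and the comparison asks which liver transcripts differ once it is removed. Values for Ncor1 itself were not analysed here, so the array labels were not checked against the targeted gene. The labels call the replicates biological, but no label ties an array to an animal, so p-values measure the spread between these samples.

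Median array intensity lay between 41.0 and 44.1. Pearson correlations across genes, which are not independent replicates, were 0.994 to 0.997 within a group and 0.992 to 0.996 between groups. The number of arrays, 4 per group, limits the precision of every value. The first principal component held 33.1% of the variance and parted the groups. WT replicate 2 (-20.5) and NCOR_KO replicate 1 (-12.2) lay lowest on the second component, which held 20.4%. At its other end were NCOR_KO replicate 4 (10.7) and WT replicate 3 (9.32), so that component ran across both groups.

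Pdk4, the kinase that shuts down pyruvate dehydrogenase, had the largest rise among the genes named by the fixed rule, from a log2 intensity of 7.80 ± 0.40 in control liver to 10.79 ± 0.42 in knockout liver (SD, n = 4), a 7.97-fold difference. Fabp5, a fatty acid binding protein, rose 4.86-fold, from 7.39 ± 0.26 to 9.67 ± 0.09 (SD, n = 4), a log2 change of 2.28 that became 1.69 with the mean of its probe sets. Cyp17a1, a steroid hydroxylase, rose 3.91-fold, and Arntl, which encodes the clock activator BMAL1, rose 3.40-fold. The largest falls among the genes named by that rule were those of Clec2h, a C-type lectin (3.88-fold lower), of Obp2a, a lipocalin (3.62-fold lower), and of Selenbp2, a selenium binding protein (3.28-fold lower).

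Across 22180 genes, 366 changed at a limma adjusted p under 0.05, of which 181 rose and 185 fell. In each of the 366 the 4 knockout values all lay on one side of the 4 control values. That separation was seen in 10.4% of all genes, where chance gives 2.86%. A change of at least 1.5-fold was estimated for 119 genes, 73 higher and 46 lower, and 25 genes rose and 11 fell by more than 2-fold. With each array centred on its own median the split became 147 rose and 383 fell. The count of changed genes lay between 120 and 297 when single arrays were left out. It was 176, 214 and 167 without WT replicates 1, 3 and 4, and 175, 120 and 193 without NCOR_KO replicates 1, 2 and 3. Of the 93 changed genes named in the text, 37 passed in all of up to 15 alternative fits and 56 missed the threshold in at least 1. Without WT replicates 1 to 4 in turn, 46, 23, 29 and 40 of the 93 missed it, and without NCOR_KO replicates 1 to 4, 41, 47, 39 and 31 did.

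**Figure D1:**
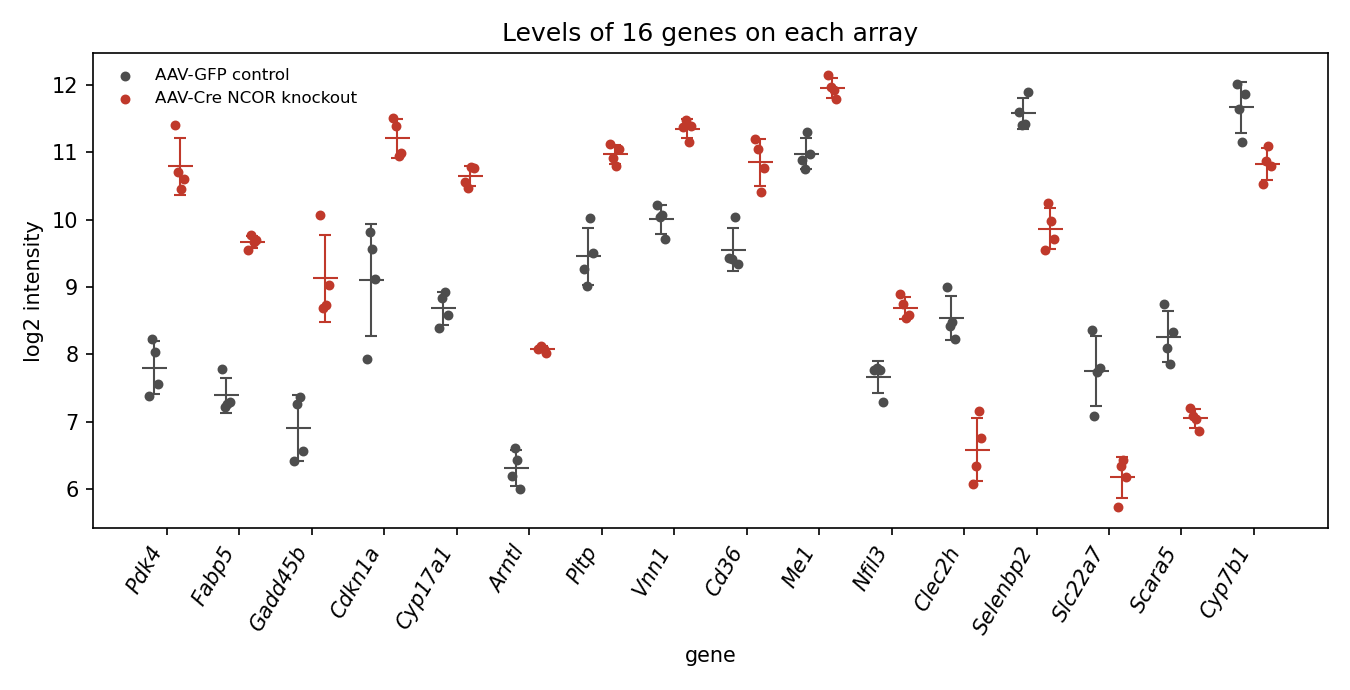
Log2 intensity (vertical axis) of 16 genes (horizontal axis) on the 4 control arrays (grey) and 4 NCOR knockout arrays (red); each point is an array, and bars give the group mean ± SD. These genes were picked from the changed genes, whose groups do not overlap, so the separation of the points follows from that choice. Group means go from Pdk4 (7.80 against 10.79) to Cyp7b1 (11.67 against 10.83).

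Among the 12 largest rises by the fixed rule, 11 passed in every alternative fit. These were Pdk4 (log2 change 2.99 ± 0.22 SE, adjusted p = 1.72e-04), Fabp5 (2.28 ± 0.12, adjusted p = 1.03e-05), Gadd45b (2.23 ± 0.31, adjusted p = 0.00790), Cyp3a59, Cyp17a1 (1.97 ± 0.12, adjusted p = 3.99e-05), Acnat2, Arntl, Pltp, Cyp2c55, Dhrs9 and Vnn1. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 4.28-fold (2.10 ± 0.34, adjusted p = 0.0149), but without NCOR_KO replicate 2 its adjusted p was 0.0641 at a log2 change of 2.04. Among the 12 largest falls, Clec2h (-1.95 ± 0.22, adjusted p = 0.00308), Selenbp2 (-1.72 ± 0.15, adjusted p = 5.92e-04), Scara5, Nlrp6, Susd4, Zfp39 and the noncoding RNA Rian passed throughout. Rian was dim, at 5.49 in control and 4.55 in knockout liver. Rian and Dhrs9 lay below the median gene level and so had 14 fits, not 15. Slc22a7, an organic anion transporter, fell by 1.58 ± 0.23 (adjusted p = 0.0105, or 0.0523 with the replicate block). Gpr155 fell by 1.18 on its brightest probe set, but the mean of its probe sets gave -0.38 with an adjusted p of 0.101, and for Zfp39 it gave -0.60 against -0.97. Obp2a, Adh6-ps1 and Krt23 lost the call in 8, 7 and 6 of the alternative fits.

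Other subunits of the NCOR complex were measured alongside. Tbl1xr1, a WD-repeat subunit, rose 1.81-fold (0.86 ± 0.08, adjusted p = 5.92e-04), and its relative Tbl1x rose 1.35-fold with an adjusted p of 0.0359 that was lost in 8 alternative fits. Hdac3, the catalytic subunit, differed by 0.04 ± 0.06 (adjusted p = 0.774). The complex list had 4 measured members, 2 of which rose and 2 did not pass. Adjusted over the list alone the counts were 2 and 0, and the list was too short for a list test.

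Of 26 measured genes of fatty acid and triglyceride synthesis 7 rose in knockout liver, 0 fell and 19 did not pass, and adjusted over the list alone 11 rose and 1 fell. Me1, the cytosolic malic enzyme that supplies NADPH, rose 1.98-fold (0.98 ± 0.12, adjusted p = 0.00353), and the elongase Elovl5 rose by 0.59 ± 0.06 (adjusted p = 0.00135). Acacb, Pnpla3 (0.96), the lipogenic regulator Srebf1 (0.60), Acaca (0.54) and the desaturase Scd1 (0.34) also rose, each losing the call in 5 to 8 alternative fits. Fasn, the fatty acid synthase, was at 0.73 ± 0.16 with an adjusted p of 0.0501. Leaving out single arrays gave adjusted p-values from 0.0380 (without WT replicate 4) to 0.120. Thrsp (0.63, adjusted p = 0.301), Elovl6 (0.50, adjusted p = 0.163), Acly (-0.25, adjusted p = 0.535) and Pklr (-0.01, adjusted p = 0.990) did not pass. The list as a whole shifted up against all other genes (camera adjusted p = 1.72e-07), with adjusted p = 0.256 with an estimated correlation. Its score split the controls, at -0.286 and -0.319 in WT replicates 1 and 2 and 0.0101 and -0.0113 in WT replicates 3 and 4. Knockout arrays scored 0.0924 to 0.224, so the size of the shift rests largely on WT replicates 1 and 2.

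In the list for lipid droplets and fatty acid uptake 5 of 24 members rose, 0 fell and 19 did not pass. Adjusted over the list alone 12 rose and 0 fell. Cd36, a fatty acid translocase, rose 2.46-fold (1.30 ± 0.19, adjusted p = 0.00903, or 0.0523 with the replicate block). Lipoprotein lipase, Lpl, rose 1.85-fold (0.88, adjusted p = 0.00888), or by 0.49 with the mean of its probe sets. The droplet coat gene Plin2 and the monoglyceride lipase gene Mgll each rose by 0.44, calls that were lost in 8 and 9 alternative fits. Cidec (1.04 ± 0.29, adjusted p = 0.111) and Mogat1 (0.16, adjusted p = 0.393) did not pass. Mogat1 was dim, at a log2 intensity of 4.78 in control and 4.94 in knockout liver, where the median gene lay at 5.88. With single arrays left out the adjusted p of Cidec ran from 0.0446 (without NCOR_KO replicate 3) to 0.259. The list shifted up (camera adjusted p = 1.72e-07), with adjusted p = 0.155 with an estimated correlation.

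Of 27 PPARα targets of peroxisomal and omega oxidation 6 rose, 0 fell and 21 did not pass, and adjusted over the list alone 12 rose. The pantetheinase gene Vnn1 rose 2.54-fold (adjusted p = 3.23e-04), the acyl-CoA thioesterase gene Acot2 2.29-fold (adjusted p = 0.00435) and Ehhadh, the peroxisomal bifunctional enzyme, 2.27-fold (1.18 ± 0.08, adjusted p = 8.88e-05). Cyp4a31 rose 1.85-fold, while Cyp4a14 was at 0.55 (adjusted p = 0.0543, or 0.0264 without WT replicate 2 and 0.04996 without WT replicate 4) and the hepatokine gene Fgf21 at 0.18 (adjusted p = 0.462). With other single arrays left out the adjusted p of Cyp4a14 reached 0.146. Fgf21 was dim, at a log2 intensity of 4.89 in control and 5.07 in knockout liver. The median gene lay at 5.88, so the missed threshold of Fgf21 says little. The list shifted up (camera adjusted p = 9.11e-09), with adjusted p = 0.172 with an estimated correlation. In mitochondrial oxidation and ketogenesis 2 of 21 members rose, Pdk4 and the carnitine acetyltransferase gene Crat (0.87, or 0.58 with the mean of its probe sets), 1 fell and 18 did not pass. Adjusted over the list alone 5 rose and 1 fell. Bdh1, a ketone body dehydrogenase, fell by 0.31, a call lost in 10 alternative fits, and Cpt1a was at -0.13 ± 0.07 (adjusted p = 0.365). The median of that list was 0.05 and its camera adjusted p 0.0125, with adjusted p = 0.507 with an estimated correlation. Without WT replicates 1 and 3 its camera adjusted p was 0.0704 and 0.0527.

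Markers of liver cell types were set beside these lipid groups. Endothelial markers had a median change of 0.18, with 19 of 21 members above 0, 1 that rose (Robo4, 0.35, lost in 9 alternative fits) and 20 that did not pass. Adjusted over the list alone 6 rose. The camera adjusted p was 1.51e-06, with adjusted p = 0.263 with an estimated correlation. Cholangiocyte markers had a median of 0.22, with 1 of 10 higher (Epcam, 0.41, lost in 10 alternative fits), 1 lower (Krt23, -0.97) and 8 not passing, and adjusted over the list alone 3 rose and 1 fell. Their camera adjusted p was 0.00470, with adjusted p = 0.144 with an estimated correlation. Hepatocyte markers were close to 0 (median -0.01, 1 of 17 lower and 16 not passing, also adjusted over the list alone). Their camera adjusted p of 0.0423 became adjusted p = 0.172 with an estimated correlation and was lost in 9 of the 15 other fits, among them those without WT replicates 2, 3 and 4 (adjusted p = 0.164, 0.0527 and 0.0528) and NCOR_KO replicates 1 and 4 (adjusted p = 0.0501 and 0.0977). The member that fell was Cebpa (-0.35, lost in 5 alternative fits), a hepatocyte transcription factor, and Alb was at 0.01 (adjusted p = 0.971).

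LXR targets, which respond to oxysterols, were higher in 5 of 18 cases, lower in 0 and not passing in 13, and adjusted over the list alone 10 rose and 1 fell. Pltp, the phospholipid transfer protein gene, rose 2.86-fold (1.52 ± 0.18, adjusted p = 0.00339), and Lpcat3 rose by 0.30, a call lost in 9 alternative fits. The other risers were Lpl, Srebf1 and Scd1, and 10 of the 18 members also stood in other lists. Abca1, the cholesterol exporter gene, was at 0.27 (adjusted p = 0.0751). The list shifted up (camera adjusted p = 2.17e-06), with adjusted p = 0.155 with an estimated correlation. In cholesterol synthesis 1 of 20 genes rose, Hsd17b7 (0.31, lost in 9 alternative fits), 0 fell and 19 did not pass, and adjusted over the list alone 1 rose and 1 fell. The list did not shift (camera adjusted p = 0.847), and its median of 0.02 and its mean of -1.75e-04 differed in sign.

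Bile acid genes went both ways. Abcb11, the bile salt export pump gene, rose 1.39-fold (0.47 ± 0.06, adjusted p = 0.00435), and Abcb4, a phospholipid exporter gene, rose by 0.38, a call lost in 9 alternative fits. Cyp7b1, an oxysterol hydroxylase gene, was 1.79-fold lower (adjusted p = 0.0449, lost in 10 alternative fits). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.44 ± 0.45 (adjusted p = 0.682), Cyp8b1 at 0.26 (adjusted p = 0.471) and Abcc4 at 1.25 (adjusted p = 0.106). Of 27 members 2 rose, 1 fell and 24 did not pass, and adjusted over the list alone 4 rose and 3 fell. The camera adjusted p was 0.545 and that of fry 0.0437. Among apolipoproteins and lipoprotein genes 1 of 20 rose, Pltp, 0 fell and 19 did not pass, and adjusted over the list alone 2 rose (camera adjusted p = 0.316, fry adjusted p = 0.00942).

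Thyroid hormone targets included Cyp17a1, Me1 and Gpd2, the mitochondrial glycerol phosphate dehydrogenase gene, which rose by 0.63. These 3 of 17 rose, 0 fell and 14 did not pass, with 3 rising adjusted over the list alone. Without NCOR_KO replicate 2 Gpd2 missed the threshold at an adjusted p of 0.05005, and with the replicate block at 0.0556. The list shifted up (camera adjusted p = 2.98e-05), with adjusted p = 0.0834 with an estimated correlation. In carbohydrate metabolism Igfbp1 rose by 0.68, a call lost with the replicate block (adjusted p = 0.0556). Pfkfb3, which drives glycolysis, fell by 0.76, a call lost in 8 alternative fits. The remaining 21 of 23 members did not pass, among them G6pc (0.03, adjusted p = 0.893) and Pck1 (-0.08, adjusted p = 0.527). Adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.366).

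**Figure D2:**
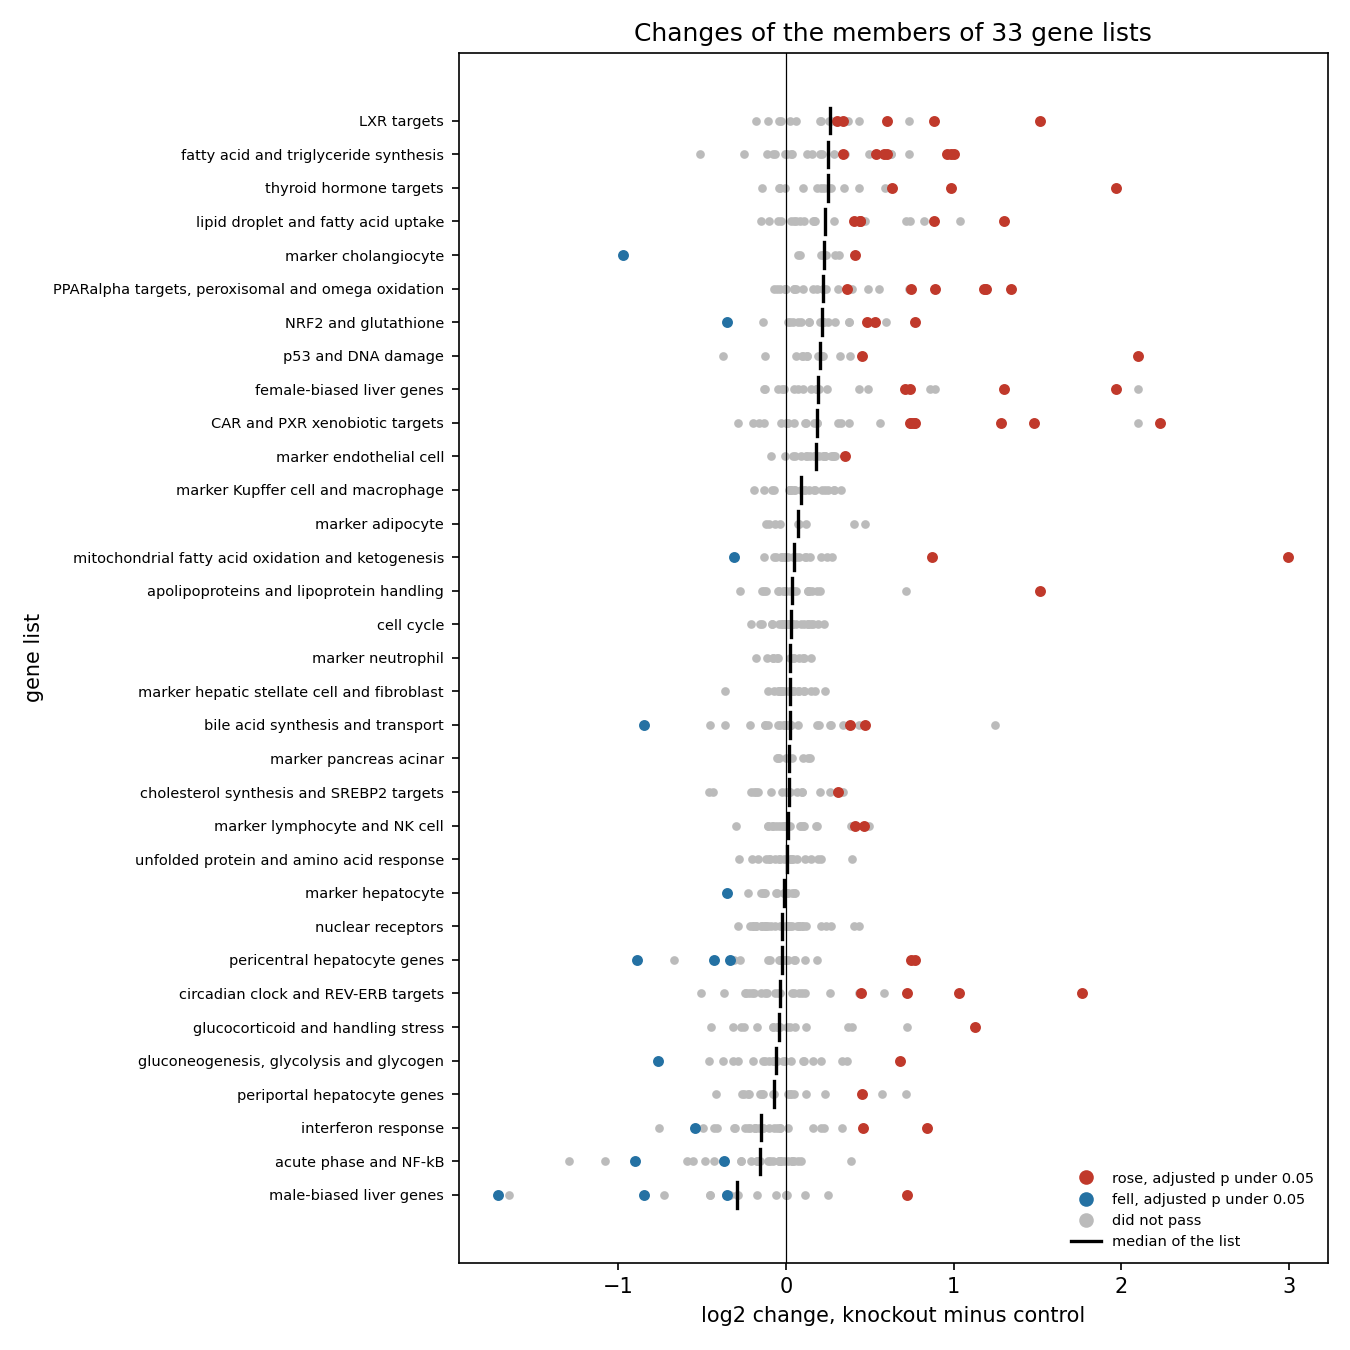
Log2 change between knockout and control liver (horizontal axis) of every measured member of 33 gene lists (vertical axis), each point a gene, with members that rose in red, that fell in blue and that did not pass in grey, and a black bar at each list's median. The medians run from -0.29 for male-biased genes to 0.26 for LXR targets.

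In the list of clock genes and REV-ERB targets 4 members were higher at this time of day. Arntl went from 6.31 ± 0.27 to 8.07 ± 0.04 (SD, n = 4; adjusted p = 5.83e-05), and Nfil3, a clock-linked repressor, rose 2.05-fold (1.03 ± 0.12, adjusted p = 0.00338). Elovl3 (0.72) and Clock (0.44) rose as well, each losing the call in 6 alternative fits. Nr1d1, which encodes REV-ERBα, was at 0.43 ± 0.18 (adjusted p = 0.274), Per3 at -0.51 (adjusted p = 0.190), Tef at -0.37 (adjusted p = 0.0660) and Dbp at -0.24 (adjusted p = 0.383). Of the 25 members 0 fell and 21 did not pass, and adjusted over the list alone 6 rose and 2 fell. The list did not pass with camera (adjusted p = 0.397) and passed with fry (adjusted p = 0.0437), and its median of -0.04 opposed its mean of 0.13 and the upward direction of the test.

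**Figure D3:**
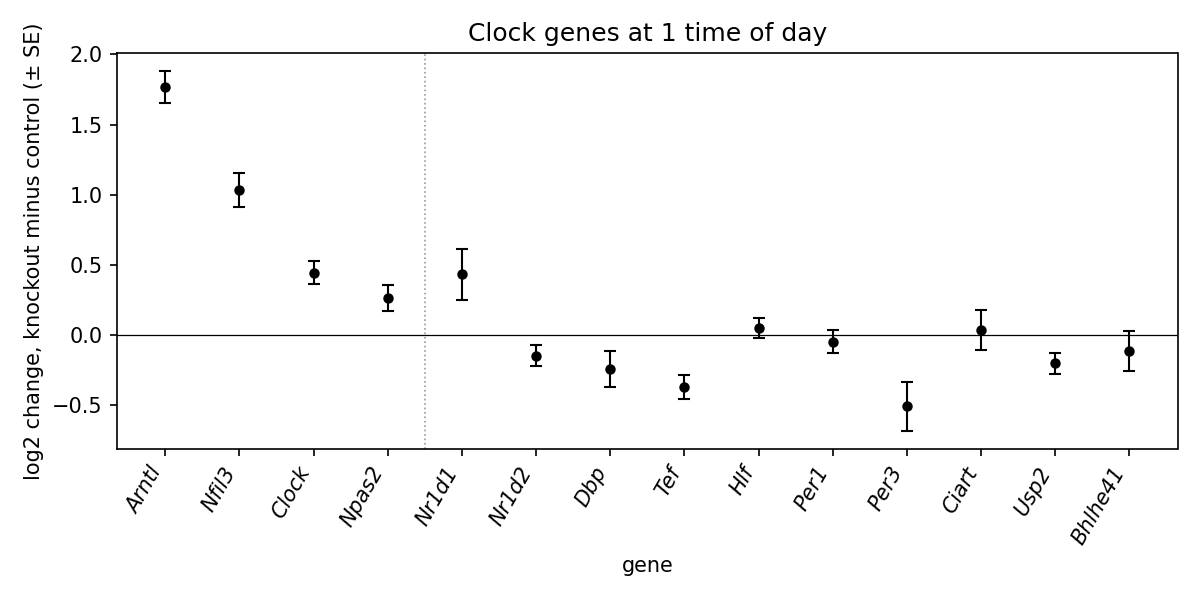
Log2 change between knockout and control liver (vertical axis; points are estimates and bars ± SE, 4 arrays per group) of 14 clock genes (horizontal axis), with Arntl, Nfil3, Clock and Npas2 left of the dotted line. Arntl (1.77), Nfil3 (1.03) and Clock (0.44) passed the test, and the 10 genes right of the line, between -0.51 and 0.43, did not.

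Of 27 targets of the xenobiotic receptors CAR and PXR 7 rose, 0 fell and 20 did not pass. The stress-inducible gene Gadd45b rose 4.68-fold, and the cytochrome P450 genes Cyp2c55 and Cyp2c38 rose 2.79-fold and 2.43-fold (adjusted p = 0.00102 and 0.0146). The log2 change of Cyp2c55, 1.48, ran from 1.08 to 1.63 over the alternative fits and from 1.38 to 1.63 without single arrays. Gstt3, Cyp2a4 and Cyp2a5 rose by 0.76, 0.74 and 0.74, calls lost in 8, 7 and 6 alternative fits. Cyp2b9 was at 2.10 ± 0.52 (adjusted p = 0.0772). With single arrays left out its adjusted p ran from 0.0244 (without WT replicate 3) to 0.177. Adjusted over the list alone 13 rose and 1 fell. The list shifted up (camera adjusted p = 1.58e-07), with adjusted p = 0.0834 with an estimated correlation. In the NRF2 and glutathione list the glutathione transferase genes Gstm3 (1.71-fold), Gstm2 (0.53) and Gstm4 (0.48) rose and Gstp1 fell by 0.35, the last 3 losing the call in 2, 3 and 7 alternative fits. That made 3 of 20 higher, 1 lower and 16 not passing, and adjusted over the list alone 7 rose and 1 fell. Its camera adjusted p was 2.98e-05, with adjusted p = 0.287 with an estimated correlation. Probe sets of near-identical Cyp and Gst paralogs can share signal, so single members of these families are uncertain.

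In the p53 list Cdkn1a and the death receptor gene Tnfrsf10b (0.45, lost in 7 alternative fits) rose, 0 of 16 fell and 14 did not pass, and adjusted over the list alone 3 rose and 1 fell. The camera adjusted p was 3.15e-04, with adjusted p = 0.0834 with an estimated correlation. Tnfrsf10b was dim, at a log2 intensity of 4.64 in control and 5.10 in knockout liver. Cell cycle genes (27 measured, largest member Foxm1 at 0.23, adjusted p = 0.263) and genes of the unfolded protein and amino acid response (21 measured, largest member Atf5 at 0.40, adjusted p = 0.121) had 0 members past the threshold, also adjusted over the list alone. Their camera adjusted p-values were 0.597 and 0.892, and the second list had a median of 0.00407 against a downward test. In the glucocorticoid and handling list Jun, an immediate early gene, rose 2.18-fold (lost in 7 alternative fits), 0 fell and 18 of 19 did not pass, and adjusted over the list alone 3 rose and 1 fell. Its camera adjusted p was 0.917, with a median of -0.04 and a downward test against a mean of 0.05.

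A few inflammatory genes changed. The chemokine gene Cxcl1 fell by 0.90 ± 0.17 (adjusted p = 0.0306) and Saa4, a constitutive serum amyloid gene, by 0.37, calls lost in 6 and 8 alternative fits. These 2 of 31 acute phase and NF-κB genes fell, 0 rose and 29 did not pass, and adjusted over the list alone 3 fell. The camera adjusted p was 2.51e-04 (down), with adjusted p = 0.516 with an estimated correlation and 0.285 with fry, and the exact permutation p of the score was 0.171. The score of WT replicate 1 (0.586) lay far above the other controls (-0.138 to 0.0495), and without it the median went from -0.16 to -0.06 (camera adjusted p = 0.0289). In the interferon list Xaf1 (1.79-fold) and Bst2 (0.46, lost in 2 alternative fits) rose, the immunoproteasome gene Psmb9 fell by 0.54 (lost in 7) and 25 of 28 did not pass, with 2 rising and 5 falling adjusted over the list alone. Without WT replicate 1 Xaf1 had an adjusted p of 0.0509. The interferon list shifted down with a camera adjusted p of 0.0248, adjusted p = 0.682 with an estimated correlation and 0.621 with fry, and the exact permutation p of its score was 0.6. Without WT replicates 3 and 4 and NCOR_KO replicate 1 its camera adjusted p was 0.161, 0.191 and 0.536.

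Among genes that differ between the sexes in mouse liver, 3 male-biased genes fell and 4 female-biased genes rose. Those of the 19 male-biased genes were Selenbp2, Cyp7b1 and Gstp1, while 1 rose (Elovl3) and 15 did not pass, and adjusted over the list alone 11 fell and 1 rose. The camera adjusted p was 6.14e-06, with adjusted p = 0.186 with an estimated correlation. Those of the 22 female-biased genes were Cyp17a1, Cd36, Cyp2a4 and Cyp3a44, while 0 fell and 18 did not pass, and adjusted over the list alone 7 rose. The camera adjusted p was 1.20e-06, with adjusted p = 0.172 with an estimated correlation. The female-biased score of WT replicate 3 (0.0852) lay nearer the knockout scores (0.122 to 0.459) than the other controls (-0.355 to -0.328) did. Cyp3a44 rose 1.64-fold (adjusted p = 0.00200). The X-inactivation RNA Xist was at 4.32 ± 0.18 in control and 4.11 ± 0.07 in knockout liver, and the Y-linked genes Eif2s3y (9.11 ± 0.08 and 9.14 ± 0.07), Uty (9.13 and 9.08) and Kdm5d (7.82 and 7.65) did not differ past the threshold either (SD, n = 4). Over all 8 arrays Xist lay at 4.01 to 4.56, Eif2s3y at 9.04 to 9.24, Uty at 8.99 to 9.24 and Kdm5d at 7.48 to 7.92. Each array thus had the pattern of male liver, which argues against a mix of sexes behind these shifts.

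Zonated genes and markers of the remaining cell types were measured too. Rhbg, a pericentral ammonium transporter gene, was 1.85-fold lower (adjusted p = 0.00921), Gulo fell by 0.43 and Cyp1a2 by 0.33, calls lost in 6 and 9 alternative fits, while Gstm3 and Cyp2a5 rose, the latter losing the call in 6. That left 15 of 20 pericentral genes not passing, with 3 rising and 6 falling adjusted over the list alone (camera adjusted p = 0.235). In the periportal list Gldc rose by 0.45 (lost in 9 alternative fits), 0 fell and 18 of 19 did not pass, with 3 rising and 2 falling adjusted over the list alone. Its camera adjusted p was 0.545, with a median of -0.07 and a downward test against a mean of 0.01. Among 22 lymphocyte and NK cell markers Cd3e (0.47) and Cd79a (0.41) rose, losing the call in 9 and 4 alternative fits, 0 fell and 20 did not pass, with 3 rising adjusted over the list alone (camera adjusted p = 0.111). With single arrays left out the camera adjusted p of that list ran from 0.0330 (without NCOR_KO replicate 1) to 0.557. Cd79a was dim, at a log2 intensity of 5.08 in control and 5.49 in knockout liver. Markers of Kupffer cells (23 measured, Vsig4 at 0.33, camera adjusted p = 0.268), stellate cells (21 measured, Lrat at -0.36, camera adjusted p = 0.597) and pancreas acinar cells (8 measured, Try4 at 0.14, camera adjusted p = 0.545) had 0 members past the threshold, also adjusted over the list alone. The Kupffer cell list passed without WT replicate 3 and without NCOR_KO replicate 1 (camera adjusted p = 0.0393 and 0.00141), and its median of 0.09 became -0.04 without WT replicate 2. Its score was lowest on WT replicate 2 (-0.475) and NCOR_KO replicate 1 (-0.298), the arrays lowest on the second component. Neutrophil markers (13 measured, Mmp8 at -0.18, camera adjusted p = 0.892) had 0 as well, with a median of 0.03 against a downward test. Adipocyte markers (9 measured, camera adjusted p = 0.545) had 0 past the threshold and 1 that rose adjusted over the list alone. Fabp4 was at 0.47 (adjusted p = 0.0749). With single arrays left out its adjusted p ran from 0.0392 (without WT replicate 3) to 0.186. The red blood cell list had 2 measured members, with Slc4a1 at -0.03. Of 33 nuclear receptor genes 0 passed, also adjusted over the list alone (median -0.02, camera adjusted p = 0.316).

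Over all lists, camera called 13 of 24 gene lists, 10 up and 3 down, and 3 of 9 marker lists. Lists shared members, so the called lists are not separate findings. Also standing in other lists were 13 of 27 CAR and PXR targets, 8 of 17 thyroid hormone targets and 8 of 22 female-biased genes. The same held for 8 of 26 synthesis genes and 6 of 27 PPARα targets. Camera with an estimated correlation called 0 gene lists and 0 marker lists, with 7 and 2 at an unadjusted p under 0.05. Fry, which asks whether the members move one way on balance, called 14 and 3. Exact permutation of the list scores gave its smallest possible p for 13 gene lists and 2 marker lists, and 0 passed after adjustment.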

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

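The tests of the clock genes, of the lipid genes and of the genes near Ncor1, and the counts of splits other than that for genes changed, were chosen only after the result was seen.

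Of 338 groups of 4 values, 19 had a single array standing far from the other 3, where chance gives 16.9. Among control arrays these were Fabp5 in WT replicate 1 (7.78, others 7.22 to 7.30), Alb in WT replicate 1 (13.48, others 13.53), Cd36 in WT replicate 3 (10.04, others 9.35 to 9.43), Gstt3 in WT replicate 3 (9.79, others 9.24 to 9.27), Nfil3 in WT replicate 4 (7.30, others 7.77 to 7.80), and in WT replicate 2 Bst2 (8.67, others 8.82 to 8.83), Slc46a3 (10.07, others 10.39 to 10.43) and the median over genes (5.78, others 5.87 to 5.89). Among knockout arrays they were Krt23 in NCOR_KO replicate 3 (5.14, others 4.79 to 4.81), Thrsp in NCOR_KO replicate 4 (11.07, others 10.65 to 10.68), Gstt3 in NCOR_KO replicate 4 (10.55, others 9.98 to 10.04), Mmp8 in NCOR_KO replicate 2 (4.64, others 4.75 to 4.77), and in NCOR_KO replicate 1 Bdh1 (9.04, others 9.22 to 9.23) and Gstp1 (12.60, others 12.42 to 12.43).

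List scores with a single array apart were those of female-biased genes in WT replicate 3 (0.0852, others -0.355 to -0.328), gluconeogenesis in WT replicate 1 (-0.114, others 0.0573 to 0.0842), cholesterol synthesis in WT replicate 2 (-0.177, others 0.0420 to 0.0801), glucocorticoid genes in NCOR_KO replicate 1 (0.107, others -0.00888 to 0.0103) and neutrophil markers in NCOR_KO replicate 4 (-0.0264, others 0.00721 to 0.0106). WT replicate 3 stood high in the female-biased score, in Cd36 and in Gstt3, but Cd36 is a member of the female-biased list and so is part of that score.

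Arntl, Nfil3 and Clock rose at a single time of day. A shift of clock phase or of collection time was looked for as a fall of clock output genes. Their median was -0.129 over 10 genes, 7 of them below 0, with 0 past the limma threshold. A median over genes that may each follow their own daily course cannot decide this at 1 time point. Fewer Nr1d1 and Nr1d2 transcripts are a candidate explanation too, but their mean change was 0.144 (SE 0.135), which left it open. That mean joins opposite signs, with Nr1d1 at 0.43 and Nr1d2 at -0.146 (limma adjusted p = 0.274 and 0.365). Weaker repression by REV-ERB without its corepressor was not tested apart from these, and with 1 time point the explanations cannot be told apart.

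Among PPARα targets 6 of 27 rose and among lipid synthesis genes 7 of 26, groups that feeding and fasting tend to move in opposite directions; with an estimated correlation the list shifts had adjusted p = 0.172 and 0.256. Less food in the knockout mice would lower the synthesis score, which was higher by 0.303 (SE 0.0916), and more food would lower the PPARα score, which was higher by 0.378 (SE 0.0750). If the lists respond that way, neither direction by itself would raise both scores, but these scores are the pattern itself and do not test feeding. The synthesis score also differed among controls, at -0.286 and -0.319 in WT replicates 1 and 2 and 0.0101 and -0.0113 in WT replicates 3 and 4. A difference in feeding between arrays was not tested separately and stays open. Over all 77 members the lipid lists had a median above that of the endothelial markers by 0.0432 (SE 0.0641). That SE takes genes as independent, so the comparison cannot decide about a larger share of endothelial RNA. Such a share stays open for the list shifts. Hepatocyte markers had a median change of -0.01. Of the 18 called lipid genes, picked for their change, 17 lay above every endothelial marker. Loss of NCOR and an effect of Cre itself stay open too, since the virus differs exactly with the group.

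Genes near Ncor1 were counted in 3 nested windows, all chosen after a look at the same genes. In the 50 tested genes around it 2 changed, and 19.4% of windows of that size held as many; in 100 genes 6 changed (2.47% of windows), and in 200 genes 9 changed (3.06% of windows). Of the counted genes Srebf1, Flcn, Tom1l2, Prpsap2 and Tmem220 lost the call in 5, 8, 9, 9 and 9 alternative fits. The window counts thus depend on the fit, and they were not repeated in the other fits. The sizes did not give the same answer, so a segment of another strain carried along with the floxed allele in one group stays open as a candidate explanation. The design text gives floxed mice to both groups while the labels call the controls wild-type, and a local effect of the deletion was not tested.

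Of the 35 splits of the arrays 1, the real one, gave as many as 366 changed genes, with 0 in the highest other split. Every other split mixes knockout and control arrays, so the group difference enters its spread and lowers its count. A share of 1 in 35 is the smallest these splits can give, so it speaks against chance for that count without excluding it. The 119 genes changed 1.5-fold are part of that count, so their result, 1 of 35 splits as large and 0 in the highest other, adds nothing to it. For gene lists 2 of 35 splits gave as many as 13, the highest other 13, and for marker lists 10 of 35 gave as many as 3, the highest other 4, so chance cannot be excluded for the counts of lists. The median of the other splits was 5.5 gene lists and 1 marker list, though 0 genes changed in any of them. Camera at its preset correlation thus called lists also where no gene passed.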

How the results depend on the processing

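Leaving out both arrays farthest out on the second component, WT replicate 2 and NCOR_KO replicate 1, was the only test here chosen after the result was seen, and it gave 202 changed genes. The 366 changed genes became 155 with the replicate block, 551 among the 11090 genes at or above the median level, 88 at an adjusted p under 0.01 and 807 under 0.1. Tested singly, 160 of the 41345 probe sets passed, a count that includes those without a gene and any controls. Without single arrays the count ran from 120 to 297. The thresholds act by construction; for the other settings the cause was not tested. The replicate numbers did not pair the arrays: deviations of equal number correlated at -0.0935 to 0.0167, and 0 arrays correlated best with their own number. Quantile normalization, centring, trend, weights and the mean of probe sets gave 340, 530, 444, 497 and 367, and shared 308, 325, 348, 358 and 356 genes with the 366; the block shared 131. All 366 genes kept their direction in each alternative that tested them. Their groups did not overlap, so leaving out arrays, the block, weights, another variance setting or fewer genes could not have reversed it. Only quantile normalization, centring and the mean of probe sets could have.

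The 119 genes changed 1.5-fold became 36 with treat against 1.2-fold, a stricter test by construction, and 81 to 122 without single arrays. The share that rose, 49.5%, became 27.7% with arrays centred on their median, where the cause was not tested beyond a shift of the median gene to -0.04, and 46.8% to 57.0% without single arrays. With an estimated correlation camera called 0 gene lists and 0 marker lists; 13 of the 16 lists called kept the call in the 15 other camera fits. With fry the acute phase and interferon lists lost theirs (adjusted p = 0.285 and 0.621), while the bile acid, circadian and apolipoprotein lists passed (adjusted p = 0.0437, 0.0437 and 0.00942). Slc22a7, Cd36, Gpd2 and Igfbp1 had adjusted p-values of 0.0523, 0.0523, 0.0556 and 0.0556 with the replicate block.

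Some genes that passed in no setting changed sign. With centring Alb was at -0.038, Ciart -0.0051, Eif2s3y -0.013, G6pc -0.013 and Hdac3 -0.00173, and with array weights G6pc was at -6.96e-04. Without both arrays of the second component Alb was at -0.00370, Cyp7a1 -0.052 and G6pc -0.042. Without single arrays the ranges were Alb -0.0080 to 0.022, Ciart -0.11 to 0.12, Cyp7a1 -0.023 to 0.79, Eif2s3y -0.00251 to 0.065, G6pc -0.024 to 0.078, Hlf -5.59e-05 to 0.084, Per1 -0.094 to 0.00925, Pklr -0.17 to 0.13 and Slc4a1 -0.083 to 0.022. Their causes were not tested. With 4 arrays per group, changes under 1.5-fold were often missed in simulated data (26% called at 1.2-fold).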

Other observations

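The genes and gene families below were chosen only after the values were seen, and no test of the families is given.

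The transcripts with the largest rise and the largest fall of all have no established name. The transcribed pseudogene 9030619P08Rik rose from 7.09 to 10.90 (log2 change 3.81 ± 0.20, limma adjusted p = 1.03e-05), and the long noncoding RNA 2610507I01Rik fell from 8.10 to 5.21 (-2.90 ± 0.11, adjusted p = 1.44e-06), both past the threshold in every alternative run. Of the 366 changed genes 342 were protein coding. Near Ncor1 the autophagy kinase gene Ulk2 fell by 0.70 ± 0.08 (adjusted p = 0.00273) and Dhrs7b, an ether lipid synthesis gene, rose by 0.54 ± 0.06 (adjusted p = 0.00195). 2610507I01Rik itself, Zfp39, Flcn, Tom1l2, Prpsap2 and Tmem220, which fell, and Srebf1, which rose, lay in the same neighbourhood of 200 genes, and 70 tested genes stood between 2610507I01Rik and Ncor1. Flcn lost the call in 8 alternative fits, Tom1l2, Prpsap2 and Tmem220 in 9 each, and Srebf1 in 5.

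Changed genes were counted in families whose close members can share probe signal, so the members are not separate calls. Of 100 Cyp genes 13 changed (13.0%, against 1.65% of all genes), of 18 Gst genes 6 changed (33.3%) and of 48 Abc transporter genes 5 changed (10.4%). They included Cyp3a25 (1.09), Cyp2d40 (-0.67), Gstt1 (0.47), Abca8a (-0.57) and Abca3 (0.39), of which Abca8a passed in every alternative run. Cyp3a25, Cyp2d40, Gstt1 and Abca3 lost the call in 9, 8, 8 and 4 alternative fits. The family counts thus depend on the fit, and they were not repeated in the other fits. Of 375 Slc genes 11 changed (2.93%), among them Slc46a3 (-0.67) and Slc2a1, whose 0.34 became 0.06 with the mean of its probe sets (adjusted p = 0.757). The Ugt, Sult, Aldh, Serpin, Rpl, Rps and Ndufa families had 0 changed genes by limma.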
